A study of Mus musculus with 8 samples.

How the data were processed

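Single-cell gene expression was measured in cell suspensions of salivary glands from 8 mice, 1 library per mouse, with droplet-based 5′ chemistry from 10x Genomics. Per the labels, 4 mice were B6 animals aged 64 weeks and 4 were C57BL/6.NOD-Aec1/2 animals aged 51 weeks, called susceptible to Sjögren's disease (SjD) in the sample titles and abbreviated SjD here. Each strain was represented by 2 females and 2 males. Per the labels' protocol, glands were digested with collagenase and DNase, lymphocytes were enriched on Lympholyte-M, and live cells were taken by a DAPI sort, so shares of cells describe what passed these steps and not the intact gland. Age and strain were fully confounded, and the labels gave no batch or date.

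The deposited matrices hold raw UMI counts per gene and cell barcode, which is how the authors' files were used. Per the submitters' processing notes, Cell Ranger 7.0.1 and the GRCm38 mouse genome were used upstream. The annotation release behind the counts was not given in the sources used here. Every matrix held whole numbers for 32285 genes, and together they held 34579 barcodes. The total per library ran from 5987524 to 33409556 UMIs. Gene positions came from the GENCODE vM21 annotation of GRCm38, which matched 32158 of the 32285 gene identifiers.

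Barcodes with at least 300 detected genes and at most 15% mitochondrial UMIs were kept, which removed 1705 barcodes. Doublets were scored library by library with Scrublet (expected rate 0.06) in scanpy 1.11.5. Scrublet's own threshold marked only 2 and 3 cells in the SjD male libraries, which is 0.0346% and 0.0758% of their cells, and 7 in each B6 male library. After these scores were seen, the top-scoring cells of each library were removed at a rate of 0.8% per 1000 barcodes, which took out 1569 cells and left 31305. The kept cells had library medians of 2978.5 to 4438 UMIs.

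Kept cells of all libraries were pooled without batch integration. The 3000 most variable genes, leaving out antigen receptor segments, mitochondrial and sex-linked genes, gave 30 principal components, a graph of 15 neighbours with shared-neighbour weights, and Leiden clusters at resolution 1 (leidenalg 0.10.2). This gave 34 clusters. A cluster took the name of a class from marker genes fixed before the data were examined, when at least 3 markers were detected in 20% of its cells and the mean marker score, a z-score over clusters, reached 0.7. That last threshold was set after the clusters were seen. Names are marker-based ("T-like" and so on) and are written below without the suffix. A cluster stayed unnamed when markers of another lineage outnumbered its own among its 10 leading genes, when NK markers came with Cd3e, or when it was shallow and led by no marker. This left 28 named clusters and 6 unnamed ones with 3692 cells, or 11.8%. Unnamed clusters are referred to by number. Cluster 6 was tested by itself as the unnamed cluster with the B cell receptor gene Cd79a in at least 40% of its cells. Cluster 12 also had enough cells in 7 libraries, but was tested only in the comparison within single clusters. T cells here comprise CD4, CD8, regulatory and gamma-delta clusters, and NK cells are summed with innate lymphoid cells and macrophages with monocytes.

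Raw counts were summed per library and class and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter and Benjamini-Hochberg adjustment within a class at a threshold of 0.05. The standard error of a log2 difference was its size over the square root of F, left out where F was under 0.001. Libraries needed at least 20 cells of a class. The model held sex and strain, all groups sharing 1 estimate of the spread because each had 2 libraries, or 1 for SjD males in cluster 6. A lone library of a group, there or after one was left out, was assumed to vary like the other groups. Whether the strain difference itself differed between the sexes was tested as (SjD female minus B6 female) minus (SjD male minus B6 male) in a fit with the 4 groups. CPM values are library means over summed counts, log2 fold changes are SjD against B6 or male against female, and their standard errors (SE) come from the test statistic. Shares of cells were tested with edgeR on numbers of cells, and beside it with an exact two-sided permutation test over the 70 assignments of 4 libraries against 4, whose smallest p is 0.0286. By chance alone, 2.86% of genes would have the libraries of the strains fully separated. A script checked these tests on simulated counts with 200 changed genes per class. Among genes changed by log2 1 it recovered 79% in T cells, 78.8% in B cells, 86.6% in NK and innate lymphoid cells, 73.5% in macrophages and monocytes and 38% in cluster 6. At log2 2 the recovered share was 99% in T cells and cluster 6 and 100% in the other classes. Unchanged genes called were 13 in T cells, 20 in B cells, 12 in NK and innate lymphoid cells, 7 in macrophages and monocytes and 11 in cluster 6. Except in macrophages and monocytes, this was a larger share of the calls than the threshold of 0.05.

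The groups, tests, cell markers, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. By that rule the text names, per class, up to 5 genes with the largest rise and 5 with the largest fall among genes past the threshold whose strains did not overlap and whose mean reached 20 CPM in the higher strain, leaving out receptor segments and predicted genes. Predicted genes were those with names starting with Gm plus digits or ending in Rik, so gene models such as AC133103.1 stayed in. In every class, full separation of the strains at genes named for the largest changes was a condition of naming. It is no further evidence of a strain difference. It also names the 10 genes called in the most classes with 1 direction, up to 4 members of a gene list, Dock2 in every class, and up to 5 genes per class for the difference between sexes in the strain effect. Up to 6 genes per class for the sex comparison were chosen after their values were seen.

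The 23 gene lists covered DOCK-Rac cytoskeleton, type I interferon response, interferon gamma response, MHC class I and class II presentation, cytotoxic effectors, T cell activation and checkpoint, naive and recirculating lymphocytes, follicular helper and germinal centre, Th17, B cell receptor signalling, the BAFF and APRIL system, chemokines, NF-kB and TNF response, unfolded protein response, complement and phagocytic macrophages, extracellular matrix, leukocyte adhesion of endothelium, saliva secretion, dissociation stress, mitochondrial transcripts, candidate genes of NOD intervals on chromosomes 1 and 3, and sex-linked genes. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over all lists and classes, and again with an estimated correlation. Chromosomes were compared by Fisher's exact test among all genes tested in any class.

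The alternatives included other normalisation (DESeq2's median-ratio factors in edgeR), the DESeq2 1.42.0 Wald test, no filter on low counts, no sex covariate, a block for replicate number, doublets kept, a cell filter of 500 genes and 7.5% mitochondrial UMIs, at least 50 cells, libraries thinned to equal numbers of cells, resolution 2, and leaving out each library. Antibody class of plasma cells could not be compared because no cluster was named plasma.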

Results

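Cells from the salivary glands of 8 mice were profiled by 5′ single-cell RNA sequencing to compare gene expression between B6 mice and C57BL/6.NOD-Aec1/2 mice, a congenic strain with NOD-derived intervals. These mice are used as a model of Sjögren's disease, an autoimmune disease of the salivary and lacrimal glands. The series title also names DOCK2, a guanine nucleotide exchange factor that activates Rac in blood cells. There were 2 female and 2 male mice in each strain, and each mouse gave 1 library. B6 mice were 64 weeks old and SjD mice 51 weeks old, so age and strain changed together. Total UMIs were 25533891 and 33409556 in the B6 female libraries, 5987524 and 9582329 in the B6 male libraries, 10300052 and 8447288 in the SjD female libraries, and 23416766 and 16248795 in the SjD male libraries. Between 1148 and 7903 cells per library were kept. The X-linked gene Xist, which is transcribed from the inactive X chromosome, reached 225 to 282 CPM in female libraries and at most 0.173 CPM in male ones. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y gave the same assignment in all 8 libraries.

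The 31305 kept cells formed 34 clusters, most of them lymphocytes. T cells (15782 cells) held CD8 clusters led by Gzmk and Pdcd1, by Itgae or by Eomes, CD4 clusters, a Foxp3 cluster of regulatory cells and an Il17a cluster of gamma-delta cells. Clusters 1 (Dapl1, Lef1) and 3 (Igfbp4, Lef1) held naive-like T cells. B cells numbered 7062, NK and innate lymphoid cells 2396, and macrophages and monocytes, led by C1q genes, 1881. Small clusters of duct, acinar, endothelial, dendritic and erythroid cells were also present. Of the unnamed clusters, cluster 6 (led by AC133103.1, Sox5, Il5ra and Mzb1) made up 7.89% of B6 female, 6.28% of B6 male, 5.41% of SjD female and 0.649% of SjD male cells on average. In the same order cluster 12 made up 4.22%, 1.06%, 1.46% and 0.617%, cluster 15 made up 0.0566%, 0.335%, 0.112% and 6.99%, and cluster 16 made up 0.281%, 4.93%, 1.46% and 1.31%. Cluster 20 held 0.943%, 0.497%, 0.812% and 0.332%, and cluster 24 held 0.0144%, 0%, 0.544% and 1.03%. The T cell receptor complex gene Cd3e was detected in 94.46% of cluster 12, 95.42% of cluster 15 and 46.65% of cluster 16 cells. It was detected in 18.92% of cluster 20 and 97.83% of cluster 24 cells. Clusters 12, 15, 16 and 24 were counted as T cells only where unnamed clusters were joined, so the T cell results below leave them out.

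Cell composition differed far more between the sexes than between the strains. B cells made up 35.2% ± 3.55 (SD, n = 4) of cells in females and 7.21% ± 5.15 (n = 4) in males, a log2 difference of -2.58 (edgeR adjusted p = 0.0103). NK and innate lymphoid cells were more frequent in males, at 13.8% ± 3.16 against 3.86% ± 1.65 (log2 1.86, adjusted p = 0.00594). Macrophages and monocytes were too, at 13.3% ± 2.87 against 1.86% ± 0.979 (log2 2.94, adjusted p = 0.00366). In each of these 3 classes the 4 male libraries lay on one side of the 4 female ones. The exact permutation test gave its smallest possible p of 0.0286, or 0.0667 after adjustment. Naive-like T cells of clusters 1 and 3 were 33.8% and 38.2% of cells in B6 females and 11.9% and 16.3% in SjD females. They were 1.13% and 1.21% in B6 males and 0.419% and 0.209% in SjD males. Within each sex both B6 libraries thus lay above both SjD libraries. The exact permutation p was 0.0286 for sex and 0.286 for strain, but the test of strain took no account of sex. Of 14 classes, 7 differed by sex in edgeR, the others being dendritic cells (0.211% in females and 0.656% in males, adjusted p = 0.0332), endothelial cells (adjusted p = 0.00594), cluster 12 (2.84% in females and 0.837% in males, adjusted p = 0.00612) and cluster 15 (adjusted p = 0.0466). The 47 endothelial cells made up 0% of every female library, 0.0871% and 0.055% of the B6 male and 0.346% and 0.679% of the SjD male libraries. Cluster 15 was largest in SjD male 2, at 13.4% of cells against 0.174% to 0.565% in the other male libraries (exact permutation p = 0.0571, or 0.1 after adjustment). With naive-like T and B cells left out of the total, the NK difference fell to a log2 of 0.63 (adjusted p = 0.137, with a range of 0.00102 to 0.137 over its alternatives) and the macrophage difference was 1.71 (adjusted p = 0.00575).

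Between strains, T cells were 47.6% ± 2.19 of B6 and 49.7% ± 9.35 of SjD cells (SD, n = 4 each; log2 0.05, adjusted p = 0.898). B cells were 22.1% ± 12.3 and 20.4% ± 20.2 (log2 -0.85, adjusted p = 0.337). NK and innate lymphoid cells were 7.502% ± 5.33 and 10.1% ± 6.71 (adjusted p = 0.337), and macrophages and monocytes 7.61% ± 7.92 and 7.51% ± 5.75 (adjusted p = 0.470). In edgeR, 0 of 14 classes passed, with 4 at an unadjusted p under 0.05. The permutation test gave 0 after adjustment, but with a smallest p of 0.0286 over 14 classes it could hardly give any, and it takes no account of sex. In the cluster named erythroid, 0.118% of B6 and 0.578% of SjD cells, and in cluster 24 all 4 SjD libraries lay above the B6 ones (edgeR adjusted p = 0.067 for each, exact permutation p = 0.0286, 0.2 after adjustment). Of the cells named erythroid, 48.7% carried Cd3e and 25.7% Cd79a, at 2.22 times the library median of UMIs. They may therefore not be erythroid cells alone. For the difference between the sexes in the strain effect, edgeR called 0 classes, with 2 at an unadjusted p under 0.05. These shares describe cells that passed the Lympholyte-M separation and the live sort.

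**Figure D1:**
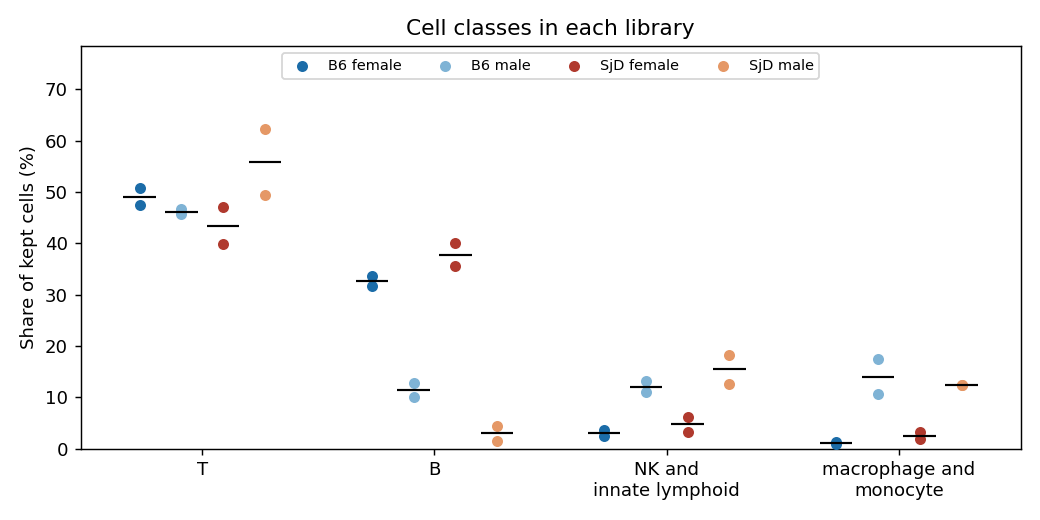
Share of kept cells (percent, y axis) held by the main cell classes (x axis), 1 point per library with bars at the group means, for B6 and SjD females and males (n = 2 each). B cell shares average 32.7% and 37.8% in B6 and SjD females, and 11.4% and 2.99% in B6 and SjD males.

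Dock2 (ENSMUSG00000020143, chromosome 11, 34226815 to 34783892 on GRCm38) was expressed at similar levels in both strains. In T cells it averaged 398 ± 35.4 CPM in B6 and 438 ± 9.71 CPM in SjD libraries (SD, n = 4 each; log2 0.14, SE 0.06, edgeR adjusted p = 0.186). Log2 differences were -0.06 (SE 0.17, adjusted p = 0.907) in B cells, 0.02 (SE 0.14, adjusted p = 0.982) in NK and innate lymphoid cells, 0.21 (SE 0.15, adjusted p = 0.609) in macrophages and monocytes, 0.05 (SE 0.19, adjusted p = 0.995) in cluster 6 and -0.02 (SE 0.17, adjusted p = 0.967) over all cells. Within females, Dock2 was 0.23 higher in SjD T cells on the log2 scale (SE 0.07, adjusted p = 0.0362), against 0.05 in males (adjusted p = 0.747), but the test of that difference between sexes gave 0.17 (adjusted p = 0.318). Clusters 1 and 3 held 71.4% and 75.3% of T cells in B6 females, 29.9% and 34.7% in SjD females and at most 2.65% in males, and without them the T cell difference was 0.04 (adjusted p = 0.712, with a range of 0.144 to 0.995 over its alternatives). In 13 single clusters Dock2 was not called. The largest separation was in the Itgae CD8 cluster 8, where all 4 SjD libraries (494 ± 45.1 CPM) lay above the B6 ones (388 ± 21.5 CPM; unadjusted p = 0.0154, adjusted p = 0.327). The B6 male 1 library had 833 CPM in B cells, against 363 to 413 CPM in the other B6 libraries, and without it the B cell difference was 0.19.

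**Figure D2:**
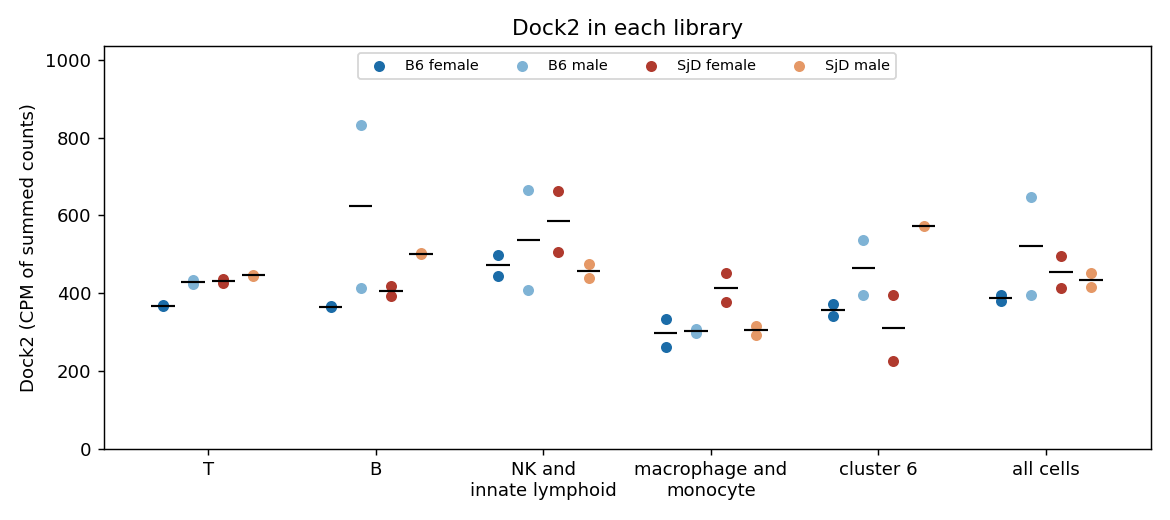
Dock2 level (CPM of summed UMIs, y axis) in each main cell class (x axis), 1 point per library with bars at the group means, for B6 and SjD females and males. B6 male 1 stands at 833 CPM in B cells, while T cell libraries lie between 368 and 447 CPM.

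In T cells, SjD mice had more Bmpr2, a receptor for bone morphogenetic proteins, at 47.2 ± 8.26 CPM against 14.998 ± 4.17 CPM in B6 (log2 1.69, SE 0.10, edgeR adjusted p = 3.66e-05). The costimulatory receptor gene Icos rose from 148 ± 28.1 to 307 ± 6.86 CPM (log2 1.08, SE 0.10, adjusted p = 5.67e-04). Ifi213, an interferon-inducible gene of the PYHIN family, was nearly undetected in SjD T cells, at 0.952 ± 0.516 CPM against 66.5 ± 18.7 CPM in B6 (log2 -6.30, adjusted p = 3.41e-07). Hey1, a transcriptional repressor downstream of Notch, fell from 21.6 ± 3.38 to 5.26 ± 1.51 CPM (log2 -2.08, adjusted p = 7.10e-05), and the LIM-domain gene Csrp1 from 79.1 ± 24.1 to 29.8 ± 1.80 CPM (log2 -1.36, adjusted p = 5.67e-04). For each of these 5 genes the 4 SjD libraries lay on one side of the 4 B6 libraries, which the naming rule required of all but Icos.

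Among the 10996 genes tested in T cells, 420 were higher and 506 lower in SjD at an adjusted p under 0.05, and 2991 had an unadjusted p under 0.05. The strains were fully separated at 1134 genes, where chance gives 2.86% of genes. Other large rises were in the organic ion transporter gene Slc22a15 (log2 1.81, adjusted p = 7.10e-05), the surface protein gene Ly6a (1.39, adjusted p = 0.00987) and the dynein light chain gene Dynlt1b (1.21, adjusted p = 0.00116). Other large falls were in Ifi206 (-1.75, adjusted p = 2.09e-04) and Ankrd50 (-1.79, adjusted p = 0.00236). All of these passed with sex in the model. Without the sex term their adjusted p lay between 0.055 and 0.129. The range over alternatives was 1.06e-41 to 0.129 for Slc22a15, 9e-38 to 0.0884 for Ly6a, 2.24e-11 to 0.0884 for Dynlt1b, 6.3e-24 to 0.0639 for Ifi206 and 4.42e-33 to 0.055 for Ankrd50. The number of called genes was 37 without the sex term, 488 without the Lef1-led clusters 1 and 3, 350 with cells thinned to the smallest library and 1749 with no filter on low counts. It was 181 without B6 female 1, 237 without B6 female 2, 218 without SjD female 1, 373 without SjD female 2 and 603 without SjD male 1.

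Of the gene lists, 4 were called in T cells. Naive and recirculating lymphocyte genes fell (1 of 11 higher, 5 lower and 5 not passing; 1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00215, but adjusted p = 0.501 with an estimated correlation). Its member Ccr7, the receptor that guides lymphocytes into lymph nodes, had 788 ± 746 CPM in B6 and 313 ± 281 CPM in SjD (log2 -1.20, SE 0.14, adjusted p = 0.00157). Clusters 1 and 3 hold different shares of T cells in the groups. Without them the list was still lower but not called (adjusted p = 0.667, range 0.00105 to 0.667 over alternatives), and Ccr7 had a log2 difference of -0.56 (adjusted p = 0.104, range 9.7e-33 to 0.558, the highest without the sex term). Unfolded protein response genes fell, with 4 of 14 lower, 0 higher and 10 not passing (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.00896, but adjusted p = 0.507 with an estimated correlation). Xbp1, a transcription factor of that response, fell from 229 ± 77.4 to 122 ± 11.4 CPM (log2 -0.85, SE 0.12, adjusted p = 0.00497). The chaperone gene Hspa5 fell from 1154 ± 299 to 796 ± 110 CPM (log2 -0.51, adjusted p = 0.0102). Without the sex term their adjusted p was 0.134 and 0.234, the highest of their alternatives, whose lowest were 1.64e-14 and 1.12e-06.

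Cytotoxic effector genes rose in T cells, with 4 of 17 higher, 0 lower and 13 not passing (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.0059, but adjusted p = 0.688 with an estimated correlation). These members were Gzma (log2 1.75, adjusted p = 0.0354), Klrg1 (0.98, adjusted p = 0.0351), Fasl (0.79, adjusted p = 0.0299) and Ctsw (0.38, adjusted p = 0.0477). The unnamed cluster 24, led by Klrg1 and Gzma, was not part of the T cell class. Without clusters 1 and 3 the list turned to lower (adjusted p = 0.961), and without SjD female 2 its adjusted p was 0.0563 (range 9.03e-04 to 0.961). Without B6 female 1 the adjusted p of these 4 genes lay between 0.117 and 0.16, without B6 female 2 between 0.0963 and 0.142, and without SjD female 1 between 0.0643 and 0.14. Leaving out SjD female 2 gave Klrg1 0.103, Fasl 0.0774 and Ctsw 0.116. Leaving out SjD male 1 gave Gzma 0.0656, Klrg1 0.0633 and Ctsw 0.0777, and leaving out B6 male 2 gave Ctsw 0.0658. Over all alternatives the adjusted p ran from 4.64e-39 to 0.248 for Gzma, 0.00321 to 0.333 for Klrg1, 1.45e-11 to 0.68 for Fasl and 0.00184 to 0.761 for Ctsw. Candidate genes of NOD intervals rose, with 3 of 14 higher, 2 lower and 9 not passing (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.0172, but adjusted p = 0.688 with an estimated correlation). Icos, Bmpr2 and Il18r1 (log2 0.75, adjusted p = 0.0105) were its higher members. Il18r1 had an adjusted p of 0.232 without the sex term and 0.0984 with unnamed clusters joined (range 7.97e-09 to 0.232). This list had an adjusted p of 0.0788 without SjD female 1, 0.0905 without SjD female 2 and 0.275 without clusters 1 and 3 (range 0.00673 to 0.688).

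In B cells, Il9r, the receptor of interleukin 9, rose from 24.2 ± 9.31 CPM in B6 to 86.001 ± 21.2 CPM in SjD (SD, n = 4 each; log2 2.22, SE 0.21, edgeR adjusted p = 2.35e-05). Csrp1 fell from 51.6 ± 6.65 to 14.4 ± 3.72 CPM (log2 -1.71, SE 0.17, adjusted p = 2.81e-05) and Ifi213 from 27.5 ± 10.0 to 2.48 ± 2.91 CPM (log2 -3.79, SE 0.37, adjusted p = 2.81e-05). Mreg (log2 -1.53, adjusted p = 8.52e-04), Rell1 (-1.43, adjusted p = 2.83e-04) and Tent5c (-1.39, adjusted p = 9.03e-05), which encodes a non-canonical poly(A) polymerase, also fell. All 4 SjD libraries were separated from the 4 B6 libraries at each of these genes, as the naming rule required. The adjusted p of Tent5c without the sex term was 0.0821, with a range of 1.55e-13 to 0.0821 over its alternatives. The gene models AC168977.2 (log2 3.49), AC125149.1 (3.35) and AC133103.1 (2.90, adjusted p = 8.32e-09) rose as well, but they lack a position in the annotation used and may share reads with near-identical copies. With cluster 6 joined to the B cells AC133103.1 no longer differed (log2 0.07, adjusted p = 0.964, with a range of 5.09e-67 to 0.964).

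Of 8845 genes tested in B cells, 169 were higher and 92 lower in SjD, 1568 had an unadjusted p under 0.05 and 744 separated the strains, where chance gives 2.86%. MHC class I presentation and interferon lists rose in B cells. For MHC class I presentation 3 of 12 members were higher, 0 lower and 9 not passing (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.00215, but adjusted p = 0.558 with an estimated correlation). Its higher members were the immunoproteasome genes Psmb8 (log2 0.56, adjusted p = 0.0187), Psmb9 (0.80, adjusted p = 0.0425) and Psmb10 (0.61, adjusted p = 0.0156). For the interferon gamma response 3 of 14 were higher, 0 lower and 11 not passing (8 higher and 0 lower adjusted over the list alone; adjusted p = 0.00522, but adjusted p = 0.501 with an estimated correlation). Among them Serpina3g rose from 69.8 ± 17.5 to 139 ± 20.7 CPM (log2 1.02, SE 0.16, adjusted p = 0.00299), and the others were Gbp5 (1.60, adjusted p = 0.0243) and Gbp7 (1.08, adjusted p = 0.0397). For the type I interferon response 1 of 13, Trim30a (log2 0.64, adjusted p = 0.0422), was higher, 0 lower and 12 not passing (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.0059, but adjusted p = 0.688 with an estimated correlation).

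Several of these B cell calls were lost when 1 library was left out, often whichever of several libraries it was. Leaving out a library also leaves fewer for the test. The interferon gamma list had an adjusted p of 0.134 without SjD female 1 and 0.108 without SjD female 2 (range 1.72e-04 to 0.501), and the type I interferon list 0.0929 without B6 male 1 and 0.317 without SjD male 1 (range 2.89e-05 to 0.688). Without B6 female 1 the adjusted p was 0.177 for Psmb8, 0.216 for Psmb9, 0.19 for Psmb10, 0.374 for Trim30a and 0.0506 for Serpina3g. Without B6 female 2 it was 0.0539, 0.0647, 0.0577 and 0.252 for the first 4 of these. Without SjD female 1 it was 0.0689, 0.109, 0.0691 and 0.126, and without SjD female 2 it was 0.0719, 0.0882, 0.0642 and 0.156. Without SjD male 1 it was 0.0504 for Psmb8, 0.12 for Psmb9 and 0.0752 for Trim30a, and without SjD male 2 it was 0.0853 for Psmb9. Gbp5 had 0.258 without B6 female 1, 0.238 without B6 female 2 and 0.051 without SjD male 2 (range 1.97e-05 to 0.258). Gbp7 had 0.322 without B6 female 1, 0.0647 without B6 female 2, 0.0587 without B6 male 2, 0.0735 without SjD male 1 and 0.0611 without SjD male 2, and lost its call under 10 of 15 alternatives (range 0.00508 to 0.322). The ranges over alternatives were 4.65e-04 to 0.177 for Psmb8, 2.96e-05 to 0.401 for Psmb9, 0.00219 to 0.401 for Psmb10, 0.00903 to 0.374 for Trim30a and 1.29e-08 to 0.373 for Serpina3g. The number of called genes was 36 without B6 female 1, 69 without B6 female 2, 485 without B6 male 1, 79 without SjD female 1 and 100 without SjD female 2. It was 86 without the sex term, 23 with thinned cells and 587 with no filter on low counts.

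In NK and innate lymphoid cells, the growth factor gene Vegfa fell from 346 ± 73.1 CPM in B6 to 60.6 ± 14.987 CPM in SjD (SD, n = 4 each; log2 -2.56, SE 0.14, edgeR adjusted p = 6.80e-11) and the granzyme gene Gzmc from 1386 ± 629 to 332 ± 106 CPM (log2 -1.92, SE 0.24, adjusted p = 3.21e-05). Ramp1, a subunit of the receptor for calcitonin gene-related peptide, rose from 47.1 ± 5.33 to 171 ± 53.7 CPM (log2 1.92, SE 0.17, adjusted p = 3.24e-07). Tnni1 (log2 -2.28, adjusted p = 5.84e-05), Mir155hg, the host transcript of microRNA 155 (-2.09, adjusted p = 2.31e-05), and the heat shock gene Hspa1a (-2.76, adjusted p = 8.93e-04) were lower. Pdcd1, which encodes the inhibitory receptor PD-1, was higher (6.06 against 23.7 CPM, log2 1.90, adjusted p = 0.00405), as were Usp21 (1.41, adjusted p = 0.00528) and Klra6 (2.08, adjusted p = 0.00238), whose reads may be split with other Klra genes. All 4 SjD libraries were separated from the B6 libraries at each of these genes, as the naming rule required. The adjusted p was 0.0551 for Pdcd1 without SjD female 1 (range 4.26e-06 to 0.0551), and without B6 male 2 it was 0.0542 for Usp21 (range 1.72e-04 to 0.0542) and 0.0659 for Hspa1a (range 1.91e-21 to 0.0659). For Mir155hg it was 0.061 without the sex term, the highest of a range from 2.55e-18.

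Of 7464 genes tested in these cells, 52 were higher and 116 lower in SjD, 1044 had an unadjusted p under 0.05 and 435 separated the strains, against a chance share of 2.86%. The lists called in these cells, all lower, were unfolded protein response, dissociation stress, and NF-kB and TNF response. Among unfolded protein response genes 3 of 14 were lower, 0 higher and 11 not passing (0 higher and 10 lower adjusted over the list alone; adjusted p = 3.7e-06, but adjusted p = 0.279 with an estimated correlation). Here Hspa5 fell from 1958 ± 257 to 995 ± 127 CPM (log2 -0.98, SE 0.10, adjusted p = 3.06e-06). Among dissociation stress genes 6 of 16 were lower, 0 higher and 10 not passing (0 higher and 14 lower adjusted over the list alone; adjusted p = 1.16e-09, but adjusted p = 0.451 with an estimated correlation). Jun fell from 937 ± 146 to 421 ± 38.1 CPM (log2 -1.18, SE 0.12, adjusted p = 1.51e-06). Among NF-kB and TNF response genes 3 of 14 were lower, 0 higher and 11 not passing (0 higher and 8 lower adjusted over the list alone; adjusted p = 2.34e-04, but adjusted p = 0.451 with an estimated correlation). The chemokine gene Cxcl2 showed the largest fall (log2 -4.14, SE 0.72, adjusted p = 0.00193). The other two were Nfkb2 (-0.52, adjusted p = 0.0235), which lost its call under 7 of 17 alternatives (range 0.0231 to 0.235), and Icam1 (-0.53, adjusted p = 0.0486), which lost it under 12 of 17 (range 0.0186 to 0.506). Without single libraries Nfkb2 had 0.0907 (B6 female 1), 0.0656 (B6 male 2), 0.0853 (SjD female 1), 0.131 (SjD male 1) and 0.106 (SjD male 2). Icam1 kept its call only without B6 male 2, and without the others its adjusted p was 0.0569 to 0.241. The number of called genes was 82 without B6 female 1, 99 without B6 male 2, 101 without SjD female 1, 65 without SjD male 1 and 98 without SjD male 2. It was 50 without the sex term, 39 with thinned cells, 293 with no filter and 106 in DESeq2.

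Single clusters showed the same direction for Hspa5, which was lower in SjD in 13 of 13 clusters tested and passed in 9.

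**Figure D3:**
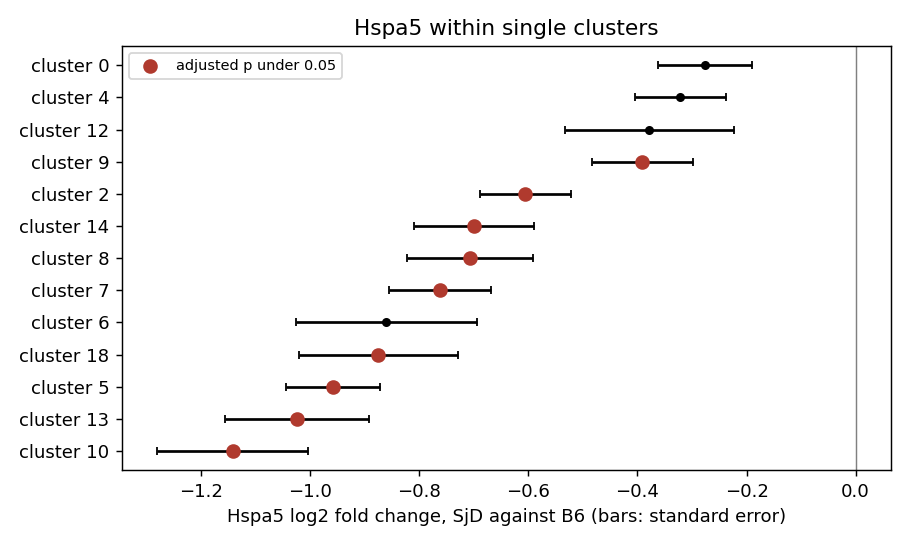
Log2 difference of Hspa5 between SjD and B6 (with standard error) in each of the 13 clusters tested. Values run from -1.142 in cluster 10 to -0.2757 in cluster 0.

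In macrophages and monocytes, the activating receptor gene Slamf7 fell from 279 ± 42.3 CPM in B6 to 29.6 ± 9.37 CPM in SjD (SD, n = 4 each; log2 -3.27, SE 0.21, edgeR adjusted p = 4.58e-07). Fcgr2b, the inhibitory Fc gamma receptor, fell from 188 ± 32.3 to 33.6 ± 10.8 CPM (log2 -2.16, SE 0.20, adjusted p = 1.67e-05), Fcrls from 31.5 ± 6.54 to 1.22 ± 1.53 CPM (log2 -3.98) and Ifi213 from 85.3 ± 16.4 to 0.746 ± 1.27 CPM (log2 -6.16, adjusted p = 3.62e-07). Chil1, which encodes a chitinase-like protein, rose from 1.11 ± 1.49 to 114 ± 99.4 CPM (log2 6.18, SE 0.56, adjusted p = 1.67e-05), the DNA annealing helicase gene Zranb3 from 5.88 ± 2.74 to 66.1 ± 20.7 CPM (log2 3.33) and Map2 from 11.8 ± 2.64 to 75.0 ± 49.7 CPM (log2 2.52, adjusted p = 0.00185). The chaperone gene Hsph1 fell (257 against 58.2 CPM, log2 -2.31, adjusted p = 0.00362), and the unplaced gene model AC133103.1 rose (log2 4.58, adjusted p = 4.01e-05). At each of these genes all 4 SjD libraries were separated from all 4 B6 libraries, as the naming rule required.

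Of 5998 genes tested in macrophages and monocytes, 20 were higher and 35 lower, 724 had an unadjusted p under 0.05 and 329 separated the strains, against a chance share of 2.86%. Unfolded protein response genes fell here too, with 3 of 14 lower, 0 higher and 11 not passing (0 higher and 8 lower adjusted over the list alone; adjusted p = 3.27e-06, but adjusted p = 0.279 with an estimated correlation). Macrophage Hspa5 fell from 2762 ± 996 to 1228 ± 380 CPM (log2 -1.16, SE 0.14, adjusted p = 4.77e-04, range 1.33e-12 to 0.126 with the highest without the sex term). Of 17 dissociation stress genes 2 were lower, 0 higher and 15 not passing (0 higher and 5 lower adjusted over the list alone; adjusted p = 0.0059, but adjusted p = 0.688 with an estimated correlation). Of 11 chemokine genes 1, Cxcl2 (2842 against 1245 CPM, log2 -1.27, adjusted p = 0.0153), was lower, 0 higher and 10 not passing (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.0336, but adjusted p = 0.507 with an estimated correlation). For the type I interferon response the list was lower with 0 of 18 members passing (0 higher and 4 lower adjusted over the list alone; adjusted p = 0.0059, but adjusted p = 0.451 with an estimated correlation). Isg15 stood at a log2 of -0.87 (adjusted p = 0.134). For mitochondrial transcripts the list was higher with 0 of 10 passing (0 higher and 0 lower adjusted over the list alone; adjusted p = 0.0336, but adjusted p = 0.688 with an estimated correlation).

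Of these macrophage lists 3 lost their call when 1 library was left out, for most of them whichever of several libraries it was. Leaving out a library also leaves fewer for the test. The dissociation list had an adjusted p of 0.0886 without B6 male 2 and 0.168 without SjD female 1 (range 8.28e-05 to 0.688). The chemokine list had 0.0834 without B6 female 2, 0.0792 without B6 male 1, 0.0886 without B6 male 2, 0.0762 without SjD female 1, 0.0754 without SjD male 1 and 0.111 without SjD male 2 (range 0.00299 to 0.507). Mitochondrial transcripts had 0.229 without B6 female 1, 0.0553 without B6 female 2, 0.188 without SjD female 1, 0.122 without SjD female 2 and 0.0582 without SjD male 2 (range 0.0157 to 0.688). Cxcl2 had 0.0525 without B6 male 2 (range 3.22e-14 to 0.21). The number of called genes was 29 without B6 male 2, 93 without SjD female 1, 87 without SjD female 2, 25 without SjD male 1 and 21 without SjD male 2. It was 19 without the sex term, 8 with thinned cells, 282 with no filter and 87 when 50 cells were required.

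In cluster 6, tested in 7 libraries because SjD male 2 held 19 of its cells, Rftn1, which encodes a lipid raft protein of B cells, fell from 1022 ± 159 CPM in B6 to 317 ± 26.6 CPM in SjD (SD, n = 4 and 3; log2 -1.70, SE 0.16, edgeR adjusted p = 8.08e-04). The lymphotoxin gene Ltb rose from 292 ± 63.9 to 683 ± 83.6 CPM (log2 1.18, SE 0.17, adjusted p = 0.0223). Ly6c2 (log2 2.47, adjusted p = 0.0223), Fcrl1 (1.11, adjusted p = 0.0306) and Rasgrp3 (1.06, adjusted p = 0.0223) also rose and the sorting nexin gene Snx5 fell (-1.09, adjusted p = 0.0142), with the 3 SjD libraries on one side of the 4 B6 ones. In this cluster 7 genes were higher and 3 lower of 7029 tested, with 674 at an unadjusted p under 0.05. Without B6 female 1 the adjusted p was 0.0989 for Fcrl1 and 0.0805 for Rasgrp3, and without B6 male 2 it was 0.0625 for Fcrl1 (ranges 4.24e-04 to 0.621 and 3.88e-04 to 0.109). With doublets kept it was 0.111 for Ly6c2 (range 1.27e-10 to 0.111) and 0.115 for Snx5 (range 2.32e-06 to 0.34), and with thinned cells 0.109 for Ltb (range 9.01e-08 to 0.109). The number of called genes was 24 without B6 female 2, 207 with no filter, 42 in DESeq2, 26 with doublets kept and 3 with thinned cells.

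Lists called in cluster 6 were type I interferon response (9 members, higher, adjusted p = 0.00215, but adjusted p = 0.558 with an estimated correlation), interferon gamma response (10 members, higher, adjusted p = 0.00595, but adjusted p = 0.501 with an estimated correlation), MHC class I presentation (12 members, higher, adjusted p = 0.0134, but adjusted p = 0.688 with an estimated correlation), DOCK-Rac cytoskeleton (16 members, higher, adjusted p = 0.00595, but adjusted p = 0.558 with an estimated correlation) and unfolded protein response (14 members, lower, adjusted p = 3e-04, but adjusted p = 0.451 with an estimated correlation). In each of them 0 members were higher and 0 lower over all genes tested. Adjusted over the list alone, 2 type I interferon, 1 interferon gamma and 1 DOCK-Rac member were higher and 5 unfolded protein response members were lower. Dock10 had 233 CPM in B6 and 369 CPM in SjD (log2 0.65, adjusted p = 0.154), and Hspa5 a log2 of -0.86 (adjusted p = 0.0879).

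Over all 23 lists, 20 of 82 tests between strains were called with the preset correlation and 0 with an estimated one, where 7 had an unadjusted p under 0.05. The DOCK-Rac cytoskeleton list was not called in T cells (3 of 16 higher, 1 lower, 12 not passing, 4 higher and 2 lower adjusted over the list alone, adjusted p = 0.121), B cells (adjusted p = 0.182), NK and innate lymphoid cells (adjusted p = 0.171) or macrophages (adjusted p = 0.773). Th17 genes in T cells had an adjusted p of 0.0538 with 2 of 9 higher, follicular helper and germinal centre genes 0.133 with 0 of 8 passing, and activation and checkpoint genes 0.184 with 2 of 15 higher. B cell receptor signalling genes in B cells (2 of 15 higher) had an adjusted p of 0.575, the BAFF and APRIL system 0.599, MHC class II presentation 0.522 and saliva secretion 0.983. Complement and phagocytic genes in macrophages had 0.798 with 0 of 8 passing, cytotoxic genes in NK cells 0.0714 with 4 of 16 higher, and sex-linked genes in T cells 0.915. Extracellular matrix and leukocyte adhesion lists had fewer than 5 tested members in every class and were not tested.

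Of the genes called between strains, Tpm3-rs7 and Snx5 were called in all 5 classes. Tpm3-rs7 (ENSMUSG00000058126, chromosome 14, 113314608 to 113316754), a sequence related to the tropomyosin gene Tpm3, rose from 1.23 ± 0.732 to 61.2 ± 5.18 CPM in T cells (log2 5.90, SE 0.18, edgeR adjusted p = 1.16e-07). Its log2 difference was 5.47 in B cells, 5.88 in NK and innate lymphoid cells, 6.36 in macrophages and 5.60 in cluster 6. Reads of Tpm3-rs7 may be shared with Tpm3, so its level is uncertain. Snx5 (chromosome 2, 144250123 to 144270906) fell by 0.87 in T cells, 0.83 in B cells, 1.01 in NK and innate lymphoid cells, 0.90 in macrophages and 1.09 in cluster 6 on the log2 scale. It was lower in 13 of 13 single clusters and passed in 10. Its macrophage call had an adjusted p of 0.0838 without B6 male 2, 0.0852 without SjD male 1 and 0.0888 without SjD male 2 (range 7.64e-05 to 0.0888). Vegfa was lower in B (log2 -2.92), NK (-2.56), T (-1.69) and macrophage (-1.65) cells, with a macrophage adjusted p of 0.0931 without SjD male 2 (range 3.16e-08 to 0.0931) and a T cell one of 0.166 without the sex term (range 4.27e-10 to 0.166). Its B6 level was 346 CPM in NK cells, 59.5 in macrophages, 18.2 in B cells and 9.13 in T cells. The part of free RNA in the low levels was not estimated.

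Dynlt1b was higher in B (log2 1.40), NK (1.31), macrophage (1.24) and T cells. Its adjusted p without B6 male 2 was 0.0601 in NK cells (range 7.36e-04 to 0.0767) and 0.199 in macrophages, where it was also 0.192 without SjD male 1 and 0.0823 without SjD male 2 (range 1.15e-04 to 0.199). Cxcl2 and Mir155hg were each called lower in 3 classes, as were Csrp1 and Ifi213. The B6 level of Cxcl2 was 2842 CPM in macrophages, 57.3 in NK cells and 86.1 in T cells, and the part of free RNA in the last 2 was not estimated. For Mir155hg in B cells (log2 -1.68, adjusted p = 0.0207) leaving out B6 female 1, B6 female 2, SjD female 1 or SjD female 2 gave 0.128, 0.105, 0.142 and 0.112 (range 9.55e-19 to 0.329). For Cxcl2 in T cells (log2 -3.73, adjusted p = 0.0350) leaving out B6 female 1, B6 male 1, SjD female 1, SjD female 2 or SjD male 1 gave 0.107, 0.0766, 0.0909, 0.0511 and 0.0722 (range 2.29e-107 to 0.223). The stress-related genes Ddit3 and Ifrd1 were called lower in T, B, NK and macrophage cells. Ddit3 differed by log2 -0.81 in NK cells (adjusted p = 4.50e-04, range 1.78e-06 to 0.321 with the highest without the sex term) and -1.13 in macrophages (adjusted p = 0.00927; 0.0741 without SjD male 2, range 1.65e-06 to 0.221). Ifrd1 differed by -0.49 in T cells (adjusted p = 0.00878, range 3.08e-06 to 0.0815), -0.54 in NK cells (0.00593; 0.0558 without SjD male 1, range 1.45e-05 to 0.114) and -0.77 in macrophages (0.00538; 0.0542 without SjD male 2, range 5.28e-13 to 0.481). In T cells the Ddit3 call (log2 -0.61) had an adjusted p of 0.0662 without B6 female 1, 0.0535 without B6 female 2, 0.05 without B6 male 2, 0.0731 without SjD female 1, 0.0752 without SjD male 1 and 0.0654 without SjD male 2 (range 1.37e-06 to 0.376). In B cells Ddit3 (log2 -0.52) had 0.189, 0.145 and 0.0679 without B6 female 1, B6 female 2 and B6 male 2, and 0.139, 0.0688 and 0.0857 without SjD female 2, SjD male 1 and SjD male 2 (range 0.00415 to 0.308). B cell Ifrd1 (log2 -0.49) had 0.19, 0.104 and 0.066 without the same B6 libraries, and 0.0922, 0.0859, 0.0656 and 0.0857 without SjD female 1, SjD female 2, SjD male 1 and SjD male 2 (range 2.53e-04 to 0.19).

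Called genes lay more often on chromosomes 1 and 3, the chromosomes of the Aec2 and Aec1 intervals. Of 685 tested genes on chromosome 1, 149 (21.8%) were called in at least 1 class, against 9.54% elsewhere (odds ratio 2.64, 95% confidence interval 2.16 to 3.20, Fisher's exact test, adjusted p = 1.56e-18). On chromosome 3 it was 87 of 546 (15.9% against 9.97%, odds ratio 1.71, interval 1.33 to 2.17, adjusted p = 2.73e-04). No other chromosome passed, the next adjusted p being 0.154. Counting only genes at an adjusted p under 0.01 gave odds ratios of 5.19 and 2.25, and at that threshold chromosome 9 held fewer calls than elsewhere (odds ratio 0.33, adjusted p = 0.0427). Many of the named genes lie there: Bmpr2 (59763400 to 59879014), Csrp1 (135720061 to 135752232), Fcgr2b (170958617 to 170976547), Slamf7 (171632403 to 171653035), Ifi206 (173468485 to 173491041), Ifi213 (173566283 to 173599274), Pdcd1, Ramp1, Chil1, Zranb3, Map2, Mreg, Tnni1 and Usp21 on chromosome 1, and Hey1 (8663359 to 8667256), Ankrd50, Tent5c, Slc22a15, Fcrl1 and Fcrls on chromosome 3. The 10 Mb window with most calls, from 170000001 to 180000000 on chromosome 1, held 30 among 75 tested genes. Genes are not independent replicates in this test. Whether reads of NOD alleles map less well at single genes, such as Ifi213, Fcrls or Slamf7, was not tested.

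**Figure D4:**
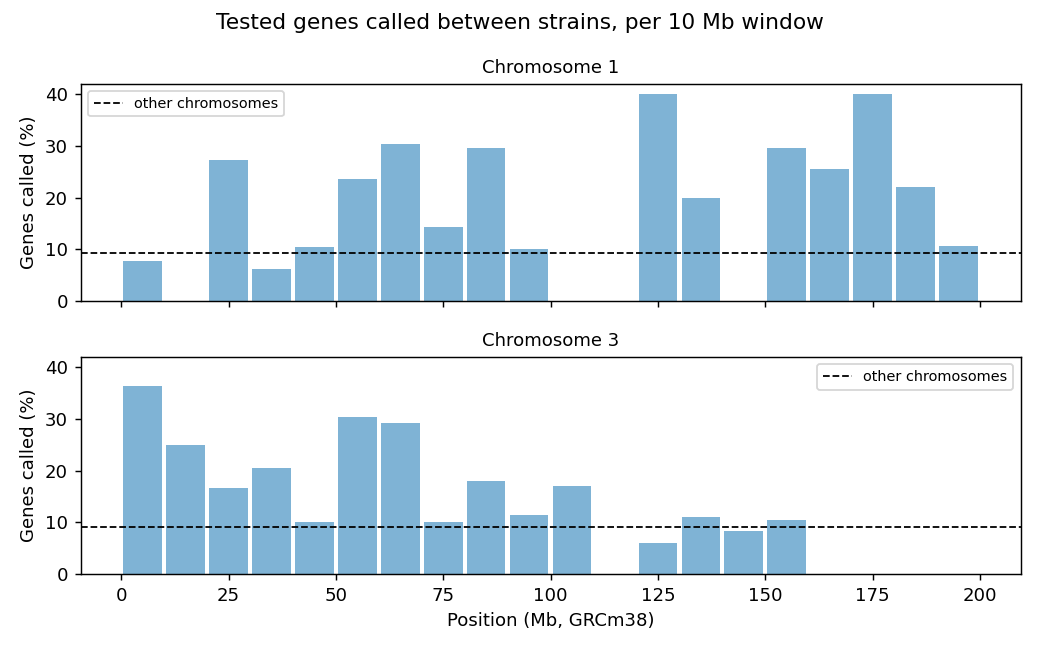
Percent of tested genes called between strains in at least 1 class (y axis) in windows of 10 Mb along chromosomes 1 and 3 (x axis, Mb on GRCm38), with gaps at windows of fewer than 10 tested genes. The line marks the share on the other chromosomes, 9.21%, which 27 of the 34 windows exceed.

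More genes were called for sex in T cells than in any other class. Male T cells had less Dapl1 (log2 -3.77, edgeR adjusted p = 1.19e-06), Igfbp4 (-5.20, adjusted p = 3.75e-05) and Plaur (-3.48, adjusted p = 2.25e-07), and more Osgin1 (3.39, adjusted p = 1.28e-05). In all, 1574 genes were higher and 1391 lower in male T cells. The mix of clusters differed by sex. In a comparison within single clusters, chosen after the data had been seen, sex calls were 10 to 109 in 6 T cell clusters. They were 218 in NK cluster 5, 35 in NK cluster 13 and 22 in macrophage cluster 10. Naive and recirculating lymphocyte genes were lower in males at 11 of 11 members (adjusted p = 8.45e-11, but adjusted p = 0.0837 with an estimated correlation), and cytotoxic effectors were higher at 12 of 17 with 0 lower and 5 not passing (adjusted p = 1.72e-06, but adjusted p = 0.487 with an estimated correlation). Adjusted over the list alone the counts were 11 lower and 12 higher. Type I interferon genes (12 of 21 higher, 1 lower, adjusted p = 8.2e-04, but adjusted p = 0.753 with an estimated correlation) were called too. In male B cells the same list was lower, with 0 of 13 members passing (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.00193, but adjusted p = 0.651 with an estimated correlation). In all, 26 list tests were called for sex and 0 with an estimated correlation, where 10 had an unadjusted p under 0.05. Clusters 1 and 3 hold at most 2.65% of male T cells, and without them 1441 genes were called and the fall of Atp1b1 (log2 -3.83, adjusted p = 2.19e-07) became -1.01 (adjusted p = 0.121, range 2.46e-83 to 0.121).

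In NK and innate lymphoid cells 140 genes were higher and 85 lower in males. Hs3st1, a heparan sulfate sulfotransferase gene (log2 -7.22, adjusted p = 6.08e-11), the growth factor gene Areg (-3.60, adjusted p = 1.58e-07) and the chymase gene Cma1 (-2.12) were lower in males. Areg is a leading gene of innate lymphoid cluster 31, on average 0.167% of B6 female, 0.126% of B6 male, 0.317% of SjD female and 0.0443% of SjD male cells. The whole class held 2.97%, 12.0%, 4.75% and 15.5% in that order, so its mix of clusters differed by sex. In B cells 75 genes were higher and 17 lower, with Lmnb1 at 1.41 (adjusted p = 6.01e-05). The shares of B cell clusters 0 and 4 among B cells differed by sex, and within them 23 and 34 genes were called. In macrophages 42 were higher and 61 lower, led by the haemoglobin gene Hbb-bs (log2 5.18, adjusted p = 2.15e-04), and in cluster 6 the counts were 7 and 4. Haemoglobin transcripts in macrophages summed to 2367 and 3322 CPM in the SjD male libraries and to at most 101.8 CPM in the others. With no filter on low counts these counts were 381 in NK cells, 468 in B cells, 425 in macrophages and 162 in cluster 6, and with thinned cells 65, 8, 3 and 3. Leaving out single libraries gave, for B cells, 42 without B6 female 1, 34 without B6 female 2, 156 without B6 male 2 and 51 without SjD female 2. For NK cells it gave 106 without B6 female 1, 146 without B6 female 2, 138 without SjD female 1 and 147 without SjD male 2, and for macrophages 50 without B6 female 2, 56 without B6 male 2, 24 without SjD female 1, 26 without SjD male 1 and 36 without SjD male 2. For cluster 6 it gave 2 without either B6 male library.

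The strain difference itself differed between the sexes for 791 T cell genes in edgeR, 530 with a larger SjD minus B6 value in females and 261 with a smaller one. S100a6, a calcium-binding protein gene, was 1.56 higher in SjD females and 0.35 in SjD males (difference 1.21, adjusted p = 0.0011), and Nrp1 1.15 and -0.17 (difference 1.32, adjusted p = 0.0011). Clusters 1 and 3 hold different shares of female T cells in the strains, and without them these differences were 0.06 (adjusted p = 0.899, range 2.06e-15 to 0.899) and 0.47 (adjusted p = 0.241, range 9.66e-11 to 0.241), and 17 genes were called. The count was 1573 with no filter, 280 with thinned cells and 401 with unnamed clusters joined. It was 323 without B6 female 1, 191 without B6 female 2, 441 without B6 male 1, 478 without B6 male 2, 510 without SjD female 1 and 388 without SjD female 2. The saliva protein genes Dcpp2 and Dcpp3, near-identical copies whose levels are uncertain, differed by -6.41 and -6.77. Gland epithelium makes these proteins, and saliva gene transcripts were counted in every cell class.

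In B cells 12 genes differed this way, in NK and innate lymphoid cells 6, in macrophages and monocytes 21 and in cluster 6 0, where 487 had an unadjusted p under 0.05 in edgeR and no other tool was run for this contrast. SjD males had 1 library in cluster 6, so this contrast has no replicate there in that group and takes its spread from the others. In B cells Mir155hg was -2.97 in females and -0.18 in males (difference -2.79, adjusted p = 7.75e-04), with 0.174 without SjD male 1 (range 1.2e-11 to 0.588). Grik3 had a larger strain value in females in NK cells (0.74 and -0.88, adjusted p = 7.57e-04). Macrophage Cd83, an activation marker, was -1.09 in females and 0.55 in males (difference -1.65, adjusted p = 0.0206), with 0.0715 without B6 female 1, 0.0635 without SjD male 1 and 0.0755 without SjD male 2 (range 3.93e-09 to 0.144). In B cells the count was 155 without B6 male 2, 19 without SjD female 1 and 1 without SjD male 1. In NK cells it was 19 without B6 male 2 and 12 without either SjD female library, and in macrophages 0 without B6 female 1 or SjD male 1, 4 without B6 female 2, 8 without SjD female 1, 53 without SjD female 2 and 2 without SjD male 2. In cluster 6 it was 6 without B6 female 1 and 14 without B6 female 2.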

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

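Of the tests below, those on tissue handling, captured cell number and lymph node tissue were chosen after the result they measure had been seen.

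The strain difference differed between females and males for 791 T cell, 12 B cell, 6 NK and innate lymphoid and 21 macrophage and monocyte genes. As log2 strain change in females minus that in males, T cell values were 1.21 for S100a6, 1.32 for Nrp1, 1.07 for Ly6a, 1.02 for Fasl, 0.48 for Ctsw and 0.73 for Ddit3. They were -0.63 for Bach2, -0.66 for Xbp1, -0.64 for Csrp1, -1.04 for Mir155hg, -1.28 for Ankrd50, -3.14 for Gm10282, -6.41 for Dcpp2 and -6.77 for Dcpp3. S100a6 and Nrp1 lost their calls without the Lef1-led clusters (adjusted p = 0.899 and 0.241). Dcpp2, Dcpp3 and Gm10282 kept theirs under all 17 alternatives. None of these alternatives removed free RNA, so this does not show that T cells express the saliva genes Dcpp2 and Dcpp3. Saliva transcripts in T cells stood at 275 and 310.3 CPM in B6 females and 68.82 and 74.2 CPM in SjD females. In males they stood at 49.79 and 117.3 CPM in B6 and 199.2 and 263.1 CPM in SjD. For the other T cell genes listed, this contrast was not followed under alternatives. Most T cell calls of this kind were lost without the Lef1-led clusters. In B cells the values were -2.79 for Mir155hg, 1.78 for Grik3, -11.02 for Igkv12-98, -10.13 for Igkv4-72 and 10.52 for Igkv8-28. The immunoglobulin values come from groups without counts, so they depend on the prior count and give no bound. Each of these 5 lost its call under 1 to 3 alternatives, with a highest adjusted p of 0.588 for Mir155hg, 0.161 for Grik3, 0.0864 for Igkv12-98, 0.825 for Igkv4-72 and 1.0 for Igkv8-28. In NK and innate lymphoid cells they were -6.46 for Gm47283, -6.89 for Dcpp2, -6.63 for Dcpp3, 1.59 for Gm19951 and 1.62 for Grik3, and Dcpp2 (highest adjusted p = 0.0545) and Gm19951 (0.108) each lost the call under 2 alternatives. In macrophages and monocytes they were 2.64 for Smpdl3b, 1.97 for Grik3, -1.75 for Rilpl2, -1.65 for Cd83 and 2.96 for Gm42031. Calls were lost under 5 alternatives for Smpdl3b (highest adjusted p = 0.141), Grik3 (0.0872) and Gm42031 (0.228), and under 4 for Rilpl2 (0.436) and Cd83 (0.144).

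Single libraries stood far from the other 3 of their strain in 9 of 124 groups of values, and chance alone gives about 1 in 20. Among cell shares these were cluster 15 in SjD male 2 (13.4%), cluster 16 in B6 male 1 (9.15%), cluster 24 in B6 female 1 (0.0287%), cluster 6 in SjD female 1 (9.26%) and erythroid cells in SjD female 2 (0.261%). Among genes they were Dock2 in B cells of B6 male 1 (833 CPM), Tpm3-rs7 in NK and innate lymphoid cells of B6 female 1 (0 CPM, others 1.40 to 1.66), Ifi213 in macrophages of SjD male 2 (2.64 CPM) and Tpm3-rs7 in macrophages of SjD female 2 (136 CPM, others 91.0 to 95.4).

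Genes called between strains were concentrated on chromosomes 1 and 3. Poorer mapping of NOD alleles to the reference would make such genes appear lower in SjD. Of those called in 1 direction, 51.95% were lower (95% confidence interval 45.3 to 58.55), against 53.19% elsewhere. This argues against poorer mapping as the main source of the excess. The share covers these genes as a set and cannot exclude poorer mapping at single genes. Ifi213, for example, fell from 66.5 to 0.952 CPM in T cells. NOD-derived intervals could give this pattern, and the 3 windows with most calls held 25% of the calls on these chromosomes and 19.5% of their tested genes. That value fell below the bound set beforehand, which counted against intervals. The bound assumed short intervals, whereas the labels give no lengths and 27 of 34 windows exceed the 9.21% of other chromosomes. The test therefore cannot count against long intervals and does not decide the question. Only the 2 chromosomes of the named intervals held an excess of calls.

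Unfolded protein response genes were lower in SjD in T, NK, macrophage and cluster 6 cells, with adjusted p = 0.507, 0.279, 0.279 and 0.451 in that order with an estimated correlation, and 4, 3, 3 and 0 of 14 members passing as lower. For Hspa5, a different mix of clusters within classes is argued against by its median difference of -0.7077 within single clusters, with 13 of 13 lower. The clusters come from the same mice and are not independent. Medians of the other members ran from -0.773 for Ddit3 to 0.115 for Pdia4, with Sec61b at 0.0218. The argument therefore does not cover every member of the list. Different handling of tissue before lysis may lower stress genes. The dissociation list was lower in 2 of these 4 classes (NK and macrophages, adjusted p = 0.451 and 0.688 with an estimated correlation) and was not called in T cells (adjusted p = 0.878) or in cluster 6, where it pointed to higher (adjusted p = 0.162), so that explanation stays open. Age differs with strain as well and cannot be separated from it.

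Naive-like T and B cells made up 47.5% to 71.8% of the female libraries and 1.70% to 13.9% of the male ones. The number of captured cells is argued against by SjD male 1, with more kept cells than either SjD female library and 4.92% of such cells. Lymph node tissue carried over with female glands might give this pattern. The ratio of B to naive-like T cells then should be similar among female libraries, but the largest was 3.39 times the smallest, while within strains this was 1.07 in B6 and 1.22 in SjD. Tissue of differing make-up in the strains is not excluded, and neither is a sex difference in the glands.

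For Tpm3-rs7, the paralog Tpm3 lost at least 50% of the CPM that Tpm3-rs7 gained in 3 of 5 classes. In B cells it lost 24.9%, and in cluster 6 Tpm3 was higher in SjD (404.5 CPM against 376.7). Outcomes of this kind were set beforehand as counting against shared reads, but they lay 0.37 and 1.29 standard errors from the 50% bound, so shared reads are not excluded.

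All 35 splits of the libraries into equal groups, or 4 against 3 in cluster 6, were fitted beside sex for the strain counts and beside strain for the sex counts. Where the split was that factor itself, it was fitted beside the tested one, a form chosen after the counts had been seen. For strain, chance is argued against in B cells, where no other split gave as many calls (261 genes, highest other split 92). This is the most that 35 splits can show. Chance cannot be excluded by this count in T cells (926 and 2965), NK and innate lymphoid cells (168 and 225), macrophages (55 and 103) and cluster 6 (10 and 11), where 2 splits were as large. The other of these was the split by sex, which points to structure among the samples. Because a labelled factor was counted among the splits, the count cannot decide there. The next highest splits gave 7, 15, 5 and 6. Fitted alone, the split by sex gave 2226, 73, 14 and 7 in these classes. For sex, chance is argued against, with 1 split as large, in T cells (2965 and 926), NK cells (225 and 168) and macrophages (103 and 55). In cluster 6 (11 and 10) 1 split was as large too, but the counts lie close. The 11 include sex-linked genes, which a split by sex calls in any case, so the count cannot exclude chance there. In B cells 2 splits reached 92, the other being the split by strain with 261 (86 alone), so this count does not exclude it there. For the 20 gene lists, chance cannot be excluded, since 5 splits gave as many and the highest other gave 29.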

How the results depend on the processing

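The alternatives that joined unnamed clusters, left out the Lef1-led clusters or left out naive-like T and B cells were chosen after the data had been seen. Each strain and sex had 2 mice, and the B6 male libraries held 1148 and 1818 cells. Of 3112 values of named genes other than Dock2 under alternatives, called or not, 2732 stayed on the same side of the threshold, 327 lost a call, 53 gained one and 0 turned direction. Calls were lost in 50 of 148 of these values without the sex term, 34 of 125 with thinned cells, 15 of 80 with unnamed clusters joined, 8 of 40 without the Lef1-led clusters, 7 of 191 with doublets kept, 6 of 132 in DESeq2 and 0 of 191 under the stricter cell filter. Of 184 list values 141 kept their call and 42 lost it, 20 of them with an estimated correlation, and 1 turned (cytotoxic effectors in T cells without the Lef1-led clusters, direction -1, adjusted p = 0.961). The cause was not tested unless stated.

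With no filter on low counts, more genes were tested and strain calls were 1749 in T, 587 in B, 293 in NK, 282 in macrophages and 207 in cluster 6. Sex calls were 468 in B, 381 in NK, 425 in macrophages and 162 in cluster 6, and strain-by-sex calls 1573, 88, 36, 148 and 107 in T, B, NK, macrophages and cluster 6. Thinned cells, with fewer counts, gave strain calls of 350, 23, 39, 8 and 3 in the same order, sex calls of 1855, 8, 65, 3 and 3, and strain-by-sex calls of 280, 1, 1 and 0 in the first 4. Without the sex term, strain calls were 37, 86, 50 and 19 in these 4. Without the Lef1-led clusters T cells had 488 strain, 1441 sex and 17 strain-by-sex calls. Joining unnamed clusters gave 32 sex and 6 strain-by-sex calls in B cells and 401 strain-by-sex calls in T cells. DESeq2 gave 106 strain calls in NK and 42 in cluster 6. Doublets kept gave 26 strain and 6 sex calls in cluster 6, 30 strain-by-sex calls in B and 8 in macrophages. The stricter filter gave 66 sex calls in macrophages, and requiring 50 cells gave 87 strain and 53 strain-by-sex calls there. That setting was not possible in cluster 6.

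Leaving out each library in turn gave strain calls of 181 to 968 in T, 36 to 485 in B, 65 to 227 in NK, 21 to 93 in macrophages and 11 to 24 in cluster 6, where 4 of 7 libraries could be left out. Strain calls moved by over 1.5 times in T cells without B6 female 1 (181), B6 female 2 (237), SjD female 1 (218), SjD female 2 (373) and SjD male 1 (603). In B cells they did without B6 female 1 (36), B6 female 2 (69), B6 male 1 (485), SjD female 1 (79) and SjD female 2 (100). In NK cells it was without B6 female 1 (82), B6 male 2 (99), SjD female 1 (101), SjD male 1 (65) and SjD male 2 (98), in macrophages without B6 male 2 (29), SjD female 1 (93), SjD female 2 (87), SjD male 1 (25) and SjD male 2 (21), and in cluster 6 without B6 female 2 (24). Sex calls ranged from 2097 to 2877 in T, 34 to 156 in B (42, 34, 156 and 51 without B6 female 1, B6 female 2, B6 male 2 and SjD female 2), 106 to 227 in NK (106, 146, 138 and 147 without B6 female 1, B6 female 2, SjD female 1 and SjD male 2), 24 to 124 in macrophages (50, 56, 24, 26 and 36 without B6 female 2, B6 male 2, SjD female 1, SjD male 1 and SjD male 2) and 2 to 13 in cluster 6 (2 without either B6 male). Strain-by-sex calls ranged from 191 to 563 in T (323, 191, 441, 478, 510 and 388 without B6 female 1, B6 female 2, B6 male 1, B6 male 2, SjD female 1 and SjD female 2), 1 to 155 in B (155, 19 and 1 without B6 male 2, SjD female 1 and SjD male 1), 6 to 19 in NK (19, 12 and 12 without B6 male 2, SjD female 1 and SjD female 2), 0 to 53 in macrophages (0, 4, 8, 53, 0 and 2 without B6 female 1, B6 female 2, SjD female 1, SjD female 2, SjD male 1 and SjD male 2) and 0 to 14 in cluster 6 (6 and 14 without B6 female 1 and B6 female 2).

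Dock2 was not called under any alternative. Over left-out libraries its log2 difference was 0.12 to 0.16 in T, -0.18 to 0.19 in B, -0.09 to 0.23 in NK, 0.09 to 0.30 in macrophages, -0.05 to 0.12 in cluster 6 and -0.11 to 0.19 over all cells. Its sign turned in B cells without B6 male 1 (0.19), in NK cells without B6 female 1 (-0.06), B6 female 2 (-0.0003385), B6 male 2 (-0.08) and SjD female 2 (-0.09135), and over all cells without B6 male 1 (0.19), SjD male 1 (0.02) and SjD male 2 (0.06). In cluster 6 it turned with no filter (-0.0238), without the sex term (-0.005467), with doublets kept (-0.02603), with thinned cells (-0.21), at cluster resolution 2 (-0.01933) and without B6 male 2 (-0.05094).

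Share differences over left-out libraries were -0.06 to 0.14 (T), -1.17 to -0.36 (B), 0.28 to 0.65 (NK) and 0.17 to 0.75 (macrophages) for strain, and 0.02 to 0.20, -2.90 to -2.09, 1.72 to 2.10 and 2.66 to 3.24 for sex, with no call ended. The T cell strain value turned with TMM factors (-0.27), without B6 male 2 (-0.003222) and without SjD male 1 (-0.06342), and the T cell sex value with TMM factors (-0.34). The macrophage strain value turned without the sex term (-0.01317). With naive-like T and B cells left out, the NK sex value was 0.63 (adjusted p = 0.137, range 0.00102 to 0.137).

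Replicate numbers do not pair mice: correlations between groups by number were -0.153 to 0.108. With a block on the number, strain calls were 544 in T, 166 in B and 25 in cluster 6, sex calls 43 in macrophages and strain-by-sex calls 8 in cluster 6, and Dock2 in cluster 6 was -0.0594. The immunoglobulin isotype result was not run because no plasma cell cluster was named.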

Other observations

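The comparison within single clusters was chosen after the data had been seen.

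Several strain differences were present within single clusters. Ly6a was higher in SjD in 9 of 9 clusters and passed in 6, with a median log2 difference of 0.976. Icos was higher in 6 of 6 and passed in 3, with a median of 0.602 against 1.08 in the T cell class, and Bmpr2 in 7 of 7 and passed in 3. Slc22a15 was higher in 7 of 8 clusters, lower in 1 and passed in 3, and its median of 0.503 was below the 1.81 of the T cell class. Csrp1 was lower in 10 of 10 clusters and passed in 4, Ifi213 in 4 of 4 and passed in 4, and Vegfa in 4 of 4 and passed in 3. Ccr7 was higher in 3 clusters and lower in 4, with 2 passing as lower. Among unfolded protein response genes Ddit3 was lower in 11 of 11 clusters and passed in 6, Xbp1 in 11 of 13 and passed in 3, and Calr in 12 of 13 and passed in 2, while Pdia4 was lower in 5 of 12 and passed as higher in 1.

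Transcripts of saliva genes were counted in T cells of every library, at 49.79 CPM in B6 male 1 up to 310.3 CPM in B6 female 2, and in macrophages of SjD female 2 at 893.1 CPM. Haemoglobin transcripts in T cells of SjD male 2 summed to 756.8 CPM.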
